A study of Mus musculus with 6 samples.

How the data were processed

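RNA was sequenced from immunoprecipitates of the protein PNMA4 made from dense fractions of mouse testis lysate. Per the series' design text, lysate of 8 testes taken at 3 months of age was spun through 25% sucrose onto 70% sucrose, and the material collected above the denser layer was separated by density on iodixanol steps, with fractions 8 and 9 going into the immunoprecipitation. The 6 libraries fall into 3 of wild type and 3 lacking PNMA4. Per the labels, replicates 1 and 2 of the group lacking PNMA4 came from Pnma4 knockout mice and replicate 3 from mice lacking both Pnma1 and Pnma4, and the submitters treated that library as the third replicate of the group. The design text calls the 3 lysates of a group biological replicates.

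The authors deposited 1 table of raw counts, with whole-number counts per Ensembl gene ID and a gene symbol for most IDs, and the counts were used as deposited. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.5.2b, featureCounts of the Subread package, DESeq2 and the mouse build GRCm38 were named, without their roles or settings. Strand settings, the handling of reads that hit several genes and the annotation release are not given in the sources used here. The table holds 57010 IDs, of which 1606 have no symbol and 34610 have a count in at least 1 library. Of the IDs, 2147 begin with ENSMUSG00002, a series that entered Ensembl after the early annotations of GRCm38, so the release behind the table is open. Of 55404 IDs with a symbol, 37636 matched the symbols of a RefSeq gene table of GRCm38.p6, which gave biotypes, neighbours and the coordinates printed here. No reference genome was used here. All 6 count columns of the table were matched to libraries by their names.

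Total counts per library ran from 3138657 to 6367930. Counting error and floors cover reads only, because reads without molecular identifiers are not independent molecules. A gene at 0 in a group was given a floor of 3 counts over the group's combined libraries (or over the library, where 1 library was at 0), and its difference was written as at least so many fold. Intervals of a share are 95% Wilson intervals. Pairs of libraries were compared with a chi-square test over genes with a summed count of at least 20. The chi-square per gene was at least 8.87 in every pair, so no library repeats another within sampling noise.

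Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a filter on low counts (filterByExpr with a minimum count of 10 and a minimum total of 15), TMM scaling factors and Benjamini-Hochberg adjustment at 0.05. The filter left 13413 genes. TMM factors ran from 0.628 in the library of the double knockout to 1.29 in wild type replicate 2. Log2 fold changes are wild type over lacking PNMA4, and a standard error is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM of the TMM-scaled library size, as mean ± SD. All adjusted p-values of single genes come from edgeR unless another tool is named. In this test, replicates 1 to 3 of the group lacking PNMA4 were 1 group, as in the labels, and a fit with the 3 genotypes as separate groups gave the contrast of the double knockout library with the Pnma4 knockout libraries.

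The design, the rule for named genes and the 23 gene lists were fixed before the data were examined. The rule named Moap1 and Pnma1, up to 12 called genes per direction whose groups do not overlap, or the 6 genes of lowest p in a direction with fewer than 6 such genes, given as values only. It also named the 8 most abundant genes and up to 4 members of each list, either those past the threshold or the 2 most abundant. Predicted genes could be summarised as a number. Results for 2 genes that the rule named are not reported here, and counts of genes include them. The genes of the contrast between knockouts and members of lists beyond this rule were named after their values were seen. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2. Benjamini-Hochberg adjustment ran over the 21 lists tested. Camera with an estimated correlation and fry were run beside it. Composition measures of whole libraries were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

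The edgeR step was tested on simulated data drawn from the real means and library sizes, with 200 of 13413 genes changed in each of 10 simulations. In these simulations it recovered 93.2% of genes changed 4-fold and 44.4% of genes changed 2-fold. The simulated genes varied independently, and many changed genes ease the Benjamini-Hochberg threshold. With 8 genes called in the real data, recovery there may be lower than these values. Above the median level of 11.2 CPM it recovered 100% and 64.9%, and below it 86.8% and 23.1%. The alternatives were DESeq2 1.42.0, 3 other scalings, limma-voom with quality weights, no filter, a filter of 50 counts in 3 libraries, mitochondrial genes left out, the replicate number as a block, the genotypes as 3 groups, a threshold of 10% and each library left out in turn. Chosen after the data were seen were leaving out rRNA-like genes, summing Moap1 with the read-through gene Gm20604, the contrast of the knockouts and the capsid gene list without Moap1 and Pnma1.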

Results

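PNMA4, named Moap1 in mouse gene tables, is a protein whose gene derives from the gag capsid gene of a retrotransposon, a class of gene whose products can assemble into particles. The data are RNA counts from immunoprecipitates of PNMA4 taken from dense, sedimentable material of mouse testis. The design asks which RNA is recovered with PNMA4 beyond what the same procedure recovers from testes without it. There are 3 wild-type libraries and 3 libraries lacking PNMA4, each from a lysate of 8 testes of mice aged 3 months. In the second group, replicates 1 and 2 are Pnma4 knockouts and replicate 3 is a double knockout of Pnma1 and Pnma4. Total counts were 3743015, 6118126 and 6089047 in wild-type replicates 1 to 3. They were 3138657, 6367930 and 4781490 in replicates 1 to 3 of the group lacking PNMA4. RNA of the lysates before immunoprecipitation was not analysed here, so a level is an abundance in the immunoprecipitate and not an enrichment over testis.

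The deleted genes were at 0 where the labels said they should be. Moap1 (ENSMUSG00000096458, chromosome 12, 102739830 to 102743661 in GRCm38.p6) had 7, 26 and 27 counts in the wild-type libraries and 0 in each library lacking PNMA4. Its wild-type level was 3.10 ± 1.17 CPM (SD, n = 3). The combined controls allow up to 0.228 CPM, so Moap1 was at least 13.6-fold higher in wild type. Pnma1 (ENSMUSG00000054383, chromosome 12, 84146131 to 84148489), a related capsid-derived gene, had 76, 140 and 139 counts in wild type and 78 and 152 in the Pnma4 knockouts. It had 0 counts in the double knockout, at least 21.1-fold below the mean of the other 5 libraries of 21.1 ± 2.51 CPM (SD, n = 5).

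The immunoprecipitates of both groups were rich in ribosomal RNA-like sequence, and Dnah8 and Akap12 were among their most abundant messenger RNAs. Rn18s-rs5, an 18S ribosomal RNA-related gene, took the largest share in all 6 libraries. It held 31.5% ± 3.60 of counts in wild type and 42.2% ± 13.3 without PNMA4 (SD, n = 3 each). Lars2, the mitochondrial leucyl-tRNA synthetase gene counted here with the rRNA-like genes, held 5.59% ± 4.29 and 7.98% ± 3.31. Dnah8 encodes an axonemal dynein heavy chain (4258 ± 461 CPM in wild type and 6665 ± 1745 without PNMA4), and Akap12 a kinase-anchoring scaffold (3652 ± 1176 and 3070 ± 853 CPM). Tdrd6, a component of the chromatoid body of spermatids, stood at 1561 ± 50.8 and 1460 ± 212 CPM. None of these genes passed the edgeR test (adjusted p = 1.00 for each).

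Single libraries stood apart in this composition. The double knockout library had 57.5% of its counts in Rn18s-rs5 (95% Wilson interval 57.45% to 57.54%), against 27.3% to 36.1% in the other 5. Lars2 held 0.751% of wild-type replicate 2 (interval 0.744% to 0.758%), against 4.34% to 10.8% elsewhere. Mitochondrially encoded genes held 1.39% ± 0.110 of counts in wild type and 1.18% ± 0.101 without PNMA4 (exact permutation p = 0.2, n = 3 each). This share is of all counts without TMM scaling, unlike the list median given later. The 10 most abundant genes held 40.9% ± 8.02 and 53.3% ± 14.0 (exact permutation p = 0.3, n = 3 each). At a common depth of 3138657 counts, 23430 ± 930 genes were detected in wild type and 22335 ± 1429 without PNMA4 (exact permutation p = 0.5, n = 3 each). The difference in genes detected, 1095, was 309 without the double knockout library and 1705 without replicate 2 of the group lacking PNMA4. The difference in the share of the 10 most abundant genes went from −12.4 to −4.69 and −18.4 percentage points in the same order. Of 12 measures of this kind, none reached p under 0.2 and adjusted p was 0.6 or more, in a design whose smallest p is 0.1.

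The RNA recovered from wild type differed from that of the controls in few genes. Of 13413 genes tested, 3 were higher in wild type and 5 were lower. Besides Moap1 itself, the higher genes were Rps6ka4, which encodes the stress-activated kinase MSK2, and Gm20604, a read-through gene whose span contains Moap1. The call of Moap1 was fixed in advance by its deletion in the controls, which may account for Gm20604 as well. Rps6ka4 was thus the only higher gene away from the deleted locus. The lower genes included 3 pseudogenes (Gm12666, Gm8116 and Gm2420) and Crisp1, a secreted protein abundant in the epididymis. No other capsid-derived gene and no germ cell marker of the fixed lists passed the test.

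Rps6ka4 (ENSMUSG00000118668, chromosome 19, 6829084 to 6842145) was 5.19-fold higher in wild type, at 17.4 ± 5.31 CPM against 3.57 ± 2.16 CPM (SD, n = 3 each). Its log2 fold change was 2.38 with a standard error of 0.36 (edgeR adjusted p = 0.00218), and all 3 wild-type libraries lay above all 3 controls. Without RNA from before immunoprecipitation, recovery of Rps6ka4 RNA with PNMA4 cannot be told apart from a difference in its level in testis. A strain variant linked to the knockout background, raised below for the pseudogenes, was not tested for Rps6ka4 and stays open too. Gm20604 (ENSMUSG00000041716, chromosome 12, 102739830 to 102757810) was 2.80-fold higher, at 35.5 ± 3.58 CPM against 12.9 ± 2.51 CPM (log2 fold change 1.48, standard error 0.24, edgeR adjusted p = 0.00344). Unlike Moap1, it kept 46, 70 and 42 counts in the controls. Since Moap1 lies inside it on the same chromosome interval, reads of the shared part cannot be assigned to either gene with certainty. The fitted log2 fold change of Moap1 was 7.08 (standard error 1.06, edgeR adjusted p = 0.00230), a size set by the prior count and not a bound. Without replicate 2 of the group lacking PNMA4, Gm20604 had an edgeR adjusted p of 0.0924 (1.20e-05 to 0.0924 over all alternatives).

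Among the lower genes, Crisp1 (ENSMUSG00000025431, chromosome 17, 40293758 to 40319207) had 2, 5 and 1 counts in wild type and 20, 21 and 24 without PNMA4. It was 11.9-fold lower in wild type (log2 fold change −3.57, standard error 0.56, edgeR adjusted p = 0.00244). The pseudogenes Gm12666, Gm8116 and Gm2420 had log2 fold changes of −4.71, −4.30 and −3.20 (standard errors 0.50, 0.59 and 0.45), with edgeR adjusted p of 1.65e-05, 0.000815 and 0.000842. Reads of a pseudogene can be shared with its parent gene, so these values are uncertain as to their source. Crisp1 lost its call in limma-voom (adjusted p = 0.0605, from 1.47e-07 to 0.0605 over all alternatives).

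**Figure D1:**
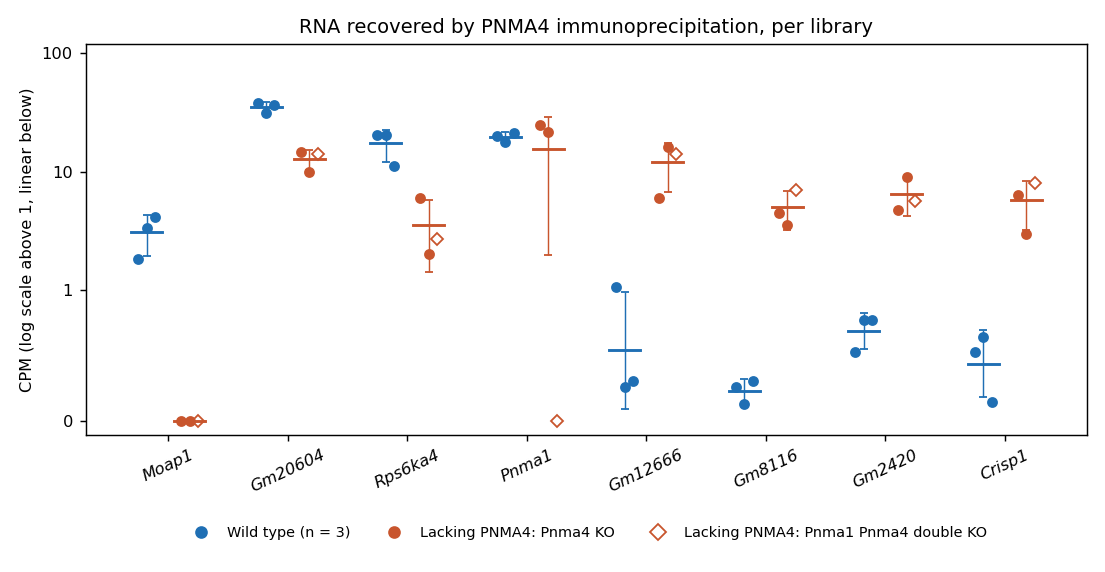
Level of 7 called genes and of Pnma1 in each library, in TMM-scaled CPM (log scale above 1, linear below). Points are libraries, horizontal lines are group means and bars are 1 SD (n = 3 per group, lower bars stopped at 0), with the double knockout drawn as an open diamond. Moap1 is at 0 in all 3 controls, Pnma1 is at 0 in the double knockout alone, and the groups do not overlap for the 7 called genes shown.

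Among genes of lowest p that did not pass, given as values only, Fnbp1l, a membrane-bending protein, stood at 54.8 ± 8.66 CPM in wild type and 25.3 ± 10.3 CPM without PNMA4 (log2 fold change 1.08, standard error 0.25, edgeR adjusted p = 0.269). The gene 4921527H02Rik had a log2 fold change of 2.40 (edgeR adjusted p = 0.0524) and Gm9271 one of 1.12 (adjusted p = 0.269). The first passed in some settings, as with upper-quartile scaling (edgeR adjusted p = 0.0416), and not in others, as in limma-voom (0.243). With 1 library left out it ran from 1.62 (edgeR adjusted p = 0.301) to 3.56 (0.00816). Fnbp1l passed without replicate 2 of the group lacking PNMA4 (0.0366). Sptbn5, a spectrin, had −1.61 (standard error 0.38, edgeR adjusted p = 0.307), and passed without the double knockout library (0.0340). In all, 7 of the 8 called genes had groups that do not overlap. Among all tested genes 898 did, or 6.7%, where chance gives 10%. At an unadjusted p under 0.05 there were 171 higher and 221 lower genes, against 671 in total expected by chance. The total depended on single libraries, with 1326 without wild-type replicate 3 and 229 to 714 in the other settings that tested the same genes. DESeq2 called 3 higher and 4 lower.

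For 9543 genes, or 71.1% of those tested, the 95% interval of the log2 fold change lay within 1 of 0. For these genes, a 2-fold difference in either direction relative to the bulk of genes is outside the interval. TMM scaling sets the bulk of genes near 0, so a difference in the total RNA recovered would not show in these values. For the rest, apart from the called genes, a 2-fold difference was not detectable or not excluded at this depth and number of libraries. Without the double knockout library 3 genes were higher and 7 lower, and without wild-type replicate 2, 7 were higher and 4 lower.

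**Figure D2:**
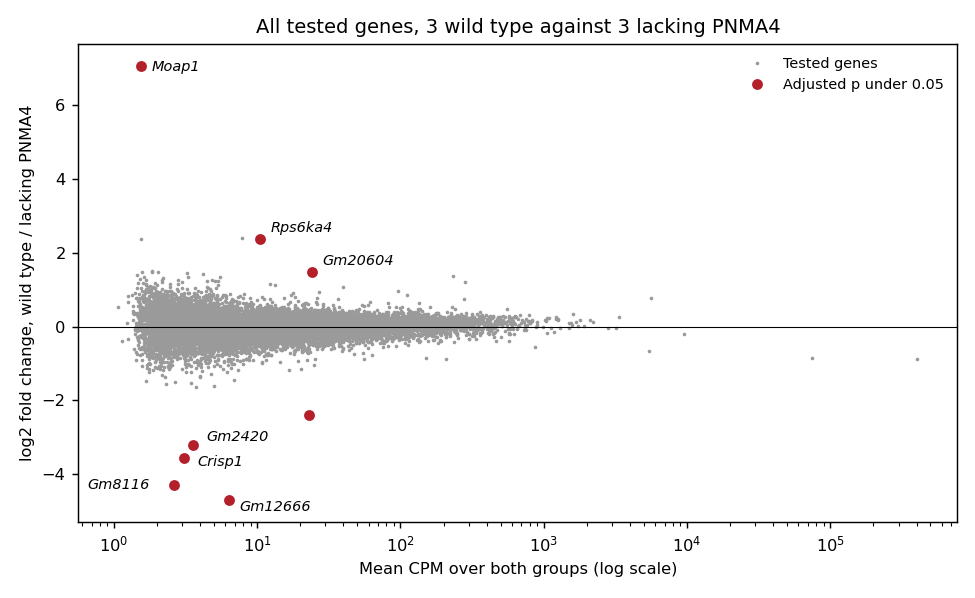
Log2 fold change, wild type over lacking PNMA4, against mean CPM over both groups (log scale) for 13413 tested genes, with the 8 genes of edgeR adjusted p under 0.05 in red and those described here named. Most genes lie near 0, and Moap1, Crisp1 and the 3 pseudogenes have mean levels under 10 CPM.

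Capsid-derived genes were the single list called higher in wild type, and the call was not kept without Moap1 and Pnma1. Of 10 tested members of the list of PNMA and other gag-derived genes, 9 had positive log2 fold changes, with a median of 0.25 that is the same with Moap1 at its bound. Moap1 alone passed the edgeR test, both over all genes and adjusted over the list alone. The synaptic capsid gene Arc stood at 139 ± 43.7 CPM in wild type and 122 ± 9.51 CPM without PNMA4, and Peg10 at 152 ± 23.9 and 140 ± 13.6 CPM. The camera test gave an adjusted p of 0.000473, and the adjusted p = 0.315 with an estimated correlation. Left without Moap1 and Pnma1, the other 8 members had a median of 0.18 (camera adjusted p = 0.0772). With the double knockout library left out as well, their median was 0.19 (camera adjusted p = 0.161).

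Lists of germ cell genes did not pass the test. The median log2 fold changes were 0.03 for 11 spermatogonia markers, −0.03 for 27 spermatocyte markers, −0.01 for 29 round spermatid markers and 0.02 for 30 elongating spermatid markers (camera adjusted p = 0.936, 0.525, 0.482 and 0.525). For the first and the last of these the mean and the test pointed the other way from the median, with means of −0.01 and −0.03. The 23 genes of the piRNA pathway and chromatoid body had a median of 0.03 and 19 sperm glycolysis genes one of −0.002 (camera adjusted p = 0.919 and 0.482). No member of these 6 lists passed the edgeR test. As examples, the meiotic cohesin gene Stag3 stood at 389 ± 74.0 and 373 ± 11.5 CPM, Odf2 of the sperm tail at 1085 ± 289 and 960 ± 56.2 CPM, and Hk1, which has a sperm form, at 1331 ± 400 and 1171 ± 186 CPM. Heat shock and chaperone genes (27 tested, median −0.06) and translation factor genes (29 tested, median −0.08) also did not pass (camera adjusted p = 0.389 and 0.194), though the second passed without wild-type replicate 1 (0.0471).

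Lists of somatic cells of the testis stood lower in wild type with all libraries and not without the double knockout library. Of 17 Leydig cell markers, genes of steroid hormone synthesis and its control, 14 had negative log2 fold changes with a median of −0.51 (camera adjusted p = 0.000421, and adjusted p = 0.616 with an estimated correlation). Of 19 Sertoli cell markers, 13 were negative with a median of −0.30 (camera adjusted p = 0.0140, and adjusted p = 0.616 with an estimated correlation). The summed level of Leydig cell markers was 827 CPM in the double knockout library and 381 ± 28.6 CPM in the other 5 (SD, n = 5). That of Sertoli cell markers was 763 CPM and 500 ± 51.7 CPM. Without that library the medians were 0.017 and 0.0015 (camera adjusted p = 0.724 and 0.811). The Sertoli cell list also did not pass without wild-type replicate 2 (adjusted p = 0.0552) or 3 (0.264, median −0.17). No member passed the edgeR test over all genes or adjusted over the list alone. Cyp17a1, which converts progestins to androgens, stood at 38.9 ± 0.846 CPM in wild type and 71.8 ± 50.1 CPM without PNMA4. Clu, secreted by Sertoli cells, stood at 99.7 ± 32.1 and 131 ± 58.8 CPM.

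Lists of ribosomal protein, respiratory chain, proteasome, histone and epididymis genes also stood lower in wild type, and again the double knockout library stood apart. Among 78 cytosolic ribosomal protein genes 64 were negative with a median of −0.27 (camera adjusted p = 1.52e-07, and 0.616 with an estimated correlation). Among 67 nuclear genes of the respiratory chain 54 were negative with a median of −0.29 (adjusted p = 9.22e-07, and 0.616 with an estimated correlation). The 31 vault and proteasome genes had a median of −0.19 and the 19 replication-dependent histone genes one of −0.37 (camera adjusted p = 0.000764 and 0.00538, and 0.616 for each with an estimated correlation). The 4 tested epididymis and sperm-tract genes had a median of −0.50 (camera adjusted p = 0.0381, and 0.616 with an estimated correlation). This list also did not pass with the replicate block (adjusted p = 0.0646), without wild-type replicate 3 (0.264, median −0.33) or without replicate 1 of the group lacking PNMA4 (median −0.62). It had 2 members lower when adjusted over the list alone, Crisp1 and the cystatin gene Cst8 (log2 fold change −0.71), and Crisp1 alone over all genes. In the double knockout library the summed levels of these 5 lists were 1.18 to 2.10 times the mean of the other 5 libraries. Without it none of the 7 lists called lower passed, with medians from −0.10 to 0.04 and a lowest adjusted p of 0.0626. Without wild-type replicate 2 the lists of vault and proteasome, ribosomal protein and respiratory chain genes still passed, with medians of −0.07, −0.17 and −0.19.

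The remaining lists did not pass in camera with all libraries, and some passed in other settings. They were peritubular, vascular and stromal markers (12 tested, median −0.27, adjusted p = 0.0846), macrophage and leukocyte markers (7 tested, median −0.18, adjusted p = 0.138), mitochondrially encoded genes (11 tested, median −0.19, adjusted p = 0.194), abundant structured noncoding RNAs (5 tested, median −0.33, adjusted p = 0.389) and apoptosis genes of the BAX and death receptor pathways. The last, which contain partners of the protein encoded by Moap1, had a median of −0.33 over 18 genes (camera adjusted p = 0.0581), and fry, which asks whether the genes of a list move 1 way on balance, gave an adjusted p of 0.00867. In camera the adjusted p = 0.616 with an estimated correlation, and the median was −0.09 with the stricter filter. With 1 library left out it lay between −0.25 and −0.04, the latter without the double knockout library. The list passed camera with the replicate block (adjusted p = 0.0497) and without scaling factors (0.0263). Their summed level was 285 ± 8.02 CPM in wild type and 323 ± 9.25 CPM without PNMA4 (SD, n = 3 each). Mitochondrially encoded genes passed with the block (camera adjusted p = 0.0146), without scaling factors (0.0240), without wild-type replicate 3 (0.0328) and without replicate 1 of the group lacking PNMA4 (0.000120), while the median was positive without wild-type replicate 1 or the double knockout library. Stromal markers passed without wild-type replicate 1 (0.0338) and without replicate 1 (0.0329) or 2 (0.00327) of the group lacking PNMA4. Structured noncoding RNAs passed without replicate 1 of that group (0.00579). Blood genes and small nuclear and nucleolar RNA genes had 2 tested members each and were not tested as lists, and none of those members passed the edgeR test. Over the 21 lists, 8 passed with the preset correlation and 0 with an estimated correlation, while fry called 1.

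**Figure D3:**
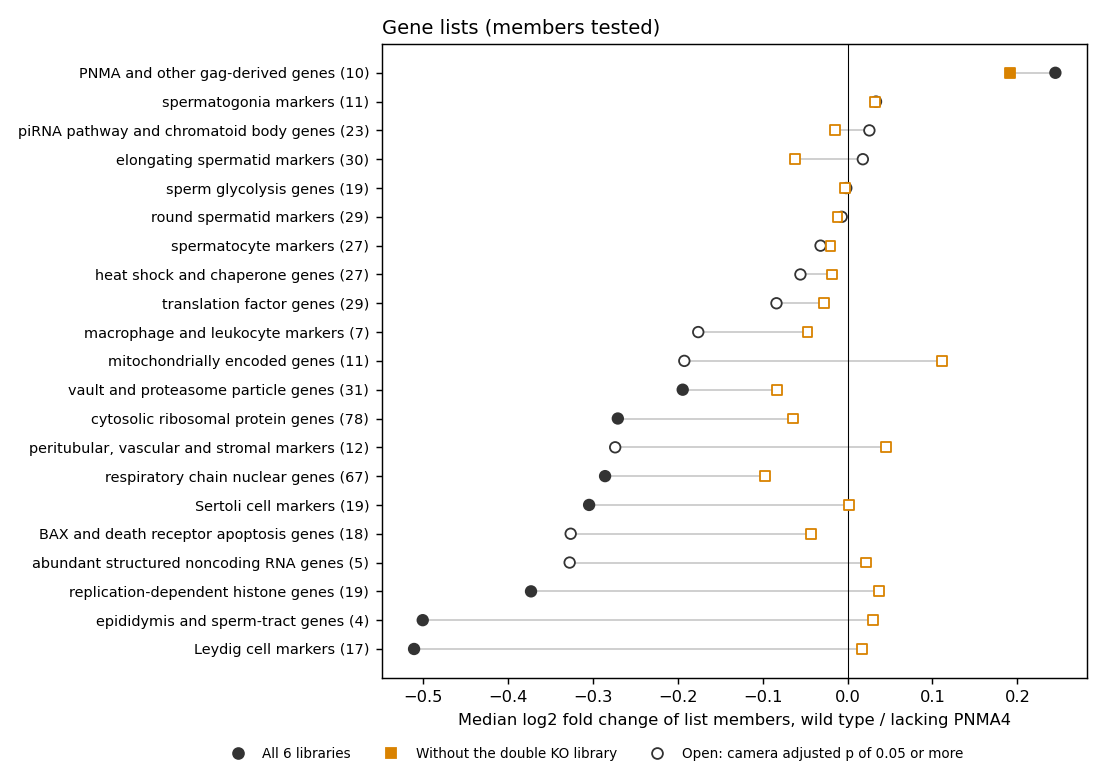
Median log2 fold change, wild type over lacking PNMA4, of the tested members of 21 gene lists (number of members in brackets), for all 6 libraries (circles) and without the double knockout library (squares). Filled symbols have a camera adjusted p under 0.05 at the preset correlation. The 7 lists filled on the lower side lie between −0.51 and −0.19 with all libraries and between −0.10 and 0.04 without that library, where the list of capsid-derived genes alone is filled. That list contains Moap1, which is deleted in the controls.

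The double knockout library also lay outside the other 5 libraries in single genes. Ptgds, a prostaglandin synthase, stood at 57.9 CPM in it and 9.22 to 17.9 CPM in the other 5, and Akr1b7, an aldose reductase-like enzyme of steroid-making cells, at 14.0 CPM against 0.429 to 2.86 CPM. Ccdc7a, Lcn2 and Alad were above the other 5 as well, with Lcn2 at 44.1 CPM against 9.71 to 15.6 CPM. Below the other 5 were Hif3a at 1.34 CPM against 6.05 to 14.3 CPM, Fam205a1 at 4.68 CPM against 25.1 to 35.8 CPM, and Pnma1. The predicted gene Gm35533 had 0 counts, at least 19.5-fold below the mean of the other 5. These genes were picked from 5 higher and 5 lower in an edgeR fit of this library against the Pnma4 knockouts, with its spread borrowed from the other genotypes. No replicate gives the spread of the double knockout, so the fit describes 1 library and is no test of the genotype.

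Lists of somatic cells and of other classes stood higher in the double knockout library than in the Pnma4 knockouts, with median log2 fold changes of 1.12 for Leydig cell, 0.93 for peritubular, vascular and stromal and 0.76 for Sertoli cell markers. The rise in TMM-scaled levels was not limited to cell markers. Medians were 0.96 for mitochondrially encoded genes, 0.80 for structured noncoding RNAs, 0.71 for epididymis genes, 0.68 for histones and 0.63 for ribosomal protein genes. The medians were −0.001 for spermatocyte and −0.004 for round spermatid markers and −0.10 for piRNA pathway and chromatoid body genes. All these values depend on the TMM factor, 0.628 in the double knockout library and 1.01 and 1.11 in the Pnma4 knockouts. As a share of all counts, mitochondrially encoded genes held 1.29% in the double knockout library and 1.12% and 1.11% in the Pnma4 knockouts. Lists were described and not tested in this contrast, since genes are not replicates of a single library. The absence of PNMA1 and the high share of Rn18s-rs5 fall in the same library and cannot be separated here.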

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

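The contrast of the double knockout library with the Pnma4 knockouts was chosen after the data were seen. Pnma1 was picked out because the double knockout library lay far from the Pnma4 knockouts, with 0 counts against 78 and 152. The fitted log2 fold change was −9.91, a size set by the prior count, and the counts support at least 21.1-fold below the mean of the other 5 libraries. The labels give a deletion of Pnma1 in that library. With 1 library of this genotype, the difference has no replicate check.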

How the results depend on the processing

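Leaving out rRNA-like genes, summing Moap1 with Gm20604 and shortening the capsid gene list were chosen after the data were seen. Over 624 recomputed values, 520 kept their direction and side of the threshold (or, for counts, stayed within 1.5 times). Of the others, 26 lost and 28 gained a call, 41 changed sign and 9 counts moved further. The 520 include values that never passed, such as Rn18s-rs5 and Lars2, so they do not measure how well calls hold. Some outcomes were fixed, since a looser threshold cannot drop a call, and the estimated correlation and fry reuse the list median. The Sertoli cell, Leydig cell, epididymis and histone lists lost their call without the double knockout library and are counted among the 41. The cause of a change was not tested except where fewer genes or libraries explain it. Moap1 stayed past 0.05 in every setting that kept it among the tested genes, with log2 fold changes of 4.63 to 7.36 and adjusted p of 2.15e-07 to 0.0366, and the stricter filter removed it. Summed with Gm20604 it had a log2 fold change of 1.61 (adjusted p = 0.00149). Rps6ka4 passed in 17 of 17 settings, Gm20604 in 16 of 17 (largest adjusted p 0.0924), Crisp1 in 15 of 16 (largest 0.0605) and the 3 pseudogenes in 16 of 16 each.

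Without a filter on low counts 11 genes were higher and 20 lower, and the stricter filter, which tests 7577 genes, left 2 higher and 0 lower (153 at an unadjusted p under 0.05). Limma-voom called 3 lower. Leaving out 1 library at a time gave 3 to 7 genes higher and 4 to 7 lower, with 7 higher without wild-type replicate 2 and 5 higher without replicate 2 of the controls. Lists past the threshold numbered 0 with an estimated correlation and 1 in fry, against 8, and 1 to 10 with a library left out (1 without the double knockout library). Without scaling factors the median of all genes moved to 0.32, and values below are relative to it.

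The fit with the replicate number as a block called 3 higher and 4 lower genes and 9 lists, with Moap1 at 7.05 (edgeR adjusted p = 0.00615). Same-numbered libraries did not deviate together (correlations of 0.04, −0.06 and 0.08 across genes), so the numbers were not taken as pairs.

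The values that changed sign passed no test under the setting that turned them. With genotypes as 3 groups, wild type over Pnma4 knockout was −0.23 for Pnma1, 0.28 for mt-Rnr2 and 0.10 for mt-Rnr1. The value of mt-Rnr1 was 0.0395 without scaling and 0.10 in limma-voom. With a library left out, ranges were −0.24 to 0.69 for Pnma1, −0.44 to 0.27 for mt-Rnr2, −0.30 to 0.14 for mt-Rnr1 and −0.0495 to 0.50 for Akap12. Medians of lists turned with the stricter filter for spermatogonia (−0.0226) and round spermatids (0.0284), and without scaling for elongating spermatids (−0.0026) and sperm glycolysis (0.0048). With a library left out, medians ran from −0.067 to 0.0673 for spermatogonia, −0.066 to 0.0123 for spermatocytes, −0.12 to 0.0758 for round and −0.0868 to 0.13 for elongating spermatids. They ran from −0.0644 to 0.12 for the piRNA pathway, −0.15 to 0.10 for glycolysis and −0.12 to 0.0355 for chaperones. The upper end of the following ranges came without the double knockout library, namely −0.44 to 0.0015 for Sertoli, −0.73 to 0.0173 for Leydig and −0.40 to 0.045 for stromal markers, −0.81 to 0.0298 for epididymis genes, −0.54 to 0.11 for mitochondrially encoded genes, −0.56 to 0.0373 for histones and −0.71 to 0.0212 for structured noncoding RNAs. At 3743015 to 6118126 counts per wild-type library, Moap1 yielded 7 to 27 reads, which limits fold estimates of genes at that level.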

Other observations

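The tests of a strain variant, of the read-through span and of the missing template were chosen after the results they bear on were seen, and the rule for carry-over of epididymis was changed after its value was seen. More genes of steroid-making cells set the double knockout library apart. Cyp17a1 stood at 128 CPM in it and at 32.1 to 55.2 CPM in the other 5 libraries, Cyp11a1, the enzyme of the first step of steroid synthesis, at 69.6 against 22.3 to 28.1 CPM, and Insl3, a Leydig cell hormone, at 61.5 against 10.6 to 28.9 CPM. No replicate gives the spread of this genotype, so these values describe 1 library. The summed level of peritubular, vascular and stromal markers was 278 CPM in that library against 128 to 179 CPM, and that of elongating spermatid markers 5642 against 4789 to 5983 CPM.

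Another division of the libraries, which mixed the 2 groups, called more genes than the real one. The real comparison had 3 genes higher and 5 lower. Of the 10 ways to split the 6 libraries into 3 and 3, 2 gave at least 3 calls in one direction and 2 gave at least 5, the real one included in each count, and the highest of the others was 22. These splits are too few for a share under 0.05. Wild-type replicates 1 and 2 with Pnma4 knockout replicate 1, against the other 3, gave 2 genes higher and 22 lower. Lower in those 3 libraries were the nuclear RNA Malat1 (log2 fold change −1.23, edgeR adjusted p = 0.0417), the Cajal body RNA Scarna10 (−1.52, adjusted p = 0.0417), the imprinted antisense RNA Kcnq1ot1 (−1.11, adjusted p = 0.0469) and the mitochondrial genes mt-Nd6, mt-Nd4 and mt-Nd3. All calls of this split had an edgeR adjusted p of 0.0417 to 0.0498. Every other split apart from the real one gave 0 or 1 calls. A structure of the samples other than the groups may lie behind this split, which was not tested.

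Moap1 and Gm20604 were higher in wild type together, and the deletion in the controls may account for both without any binding. A change of that size was not seen in the genes inside the read-through span. Their counts need not follow the read-through transcript, since strand settings and the handling of reads that hit several genes are not known. A change across the whole span therefore stays open. Tmem251 and Gon7, which lie inside the span, had 73 summed counts in wild type and 58 in the controls. Their sum had an edgeR log2 fold change of −0.007 (95% interval −0.80 to 0.79). The interval lies below the 1.48 of Gm20604 but is too wide for the bound of 0.5. This test replaced a sum that included Ubr7, at a log2 ratio of −0.14, after that value was seen, because Ubr7 lies outside the span and held most of the counts. Loss of the Moap1 template from the controls and recovery of Moap1 RNA with PNMA4 cannot be told apart, since the controls have 0 Moap1 reads whatever PNMA4 binds. Moap1 ranked at percentile 17 of tested genes by the wild-type reads assigned to it and Gm20604 at 75.8, and since the intervals overlap, neither rank gives the level of Moap1 RNA. A library of RNA before immunoprecipitation, not analysed here, would give the enrichment of Moap1 RNA in wild type. The controls would still hold no Moap1 RNA to compare it with.

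The pseudogenes and Crisp1, lower in wild type, were seen in all 3 controls, double knockout included. A strain variant linked to the knockout background may send reads to pseudogenes. There were 7 pseudogenes with reads almost only in the controls and 0 almost only in wild type, beside 11 and 33 other genes. The 7 include the called Gm12666 and Gm8116, so part of the count was fixed by the calls it is meant to explain. The called Gm2420 is not among them. Another split gave 13, but it set the 3 libraries of lowest total counts against the 3 of highest, so depth may enter it. The split of wild-type replicates 1 and 2 with Pnma4 knockout replicate 1 gave 0, against 7 in the other 3 libraries. The count therefore does not decide and this stays open. For Crisp1, carry-over of epididymis stays open. The other members of the epididymis list had a log2 ratio of −0.47, wild type over controls (counting interval −0.71 to −0.24). Against the Pnma4 knockouts alone that ratio was −0.24 (interval −0.51 to 0.03), while Crisp1 had a log2 fold change of −3.25 without the double knockout library. The rule set beforehand to count against carry-over, a ratio above −0.5 with an interval that excludes −1, was met by both ratios. After the ratio of −0.47 was seen, the rule was changed to an interval wholly above −0.5, which neither meets, so carry-over is left open by a rule made later and the earlier one would argue against it. The reasons were that −0.47 passes −0.5 by less than its interval and that the sum can hide a small share of epididymis. Most of its counts were Cst8, Eppin and other genes also read in wild type, while Adam7 had 5 counts in wild type and 22 in the controls and Defb21 had 0 and 7. Others went the other way, with 32 and 12 counts for Wfdc6a, 25 and 14 for Rnase10 and 5 and 2 for Crisp4. Lcn5, Lcn9, Defb20, Defb48 and Wfdc15b had 0 in all 6 libraries and Lcn8 had 1.

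In wild-type replicate 2, Gm15564, which shares its interval with Lars2, had 246 counts, against 6068 to 18568 in the other 5 libraries. The rRNA-like gene Mir6236 had 43462, 30568 and 38804 counts in wild-type replicates 1 to 3, 8302 and 39307 in Pnma4 knockout replicates 1 and 2, and 12263 in the double knockout. In the same order, Gm55936 had 1958, 806, 2619, 126, 1622 and 340 counts, at total counts of 3743015, 6118126, 6089047, 3138657, 6367930 and 4781490.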
